A study of Mus musculus with 4 samples.

How the data were processed

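Total RNA was extracted from mouse hearts with a column kit and made into libraries by standard Illumina protocols, per the labels' protocols. One file per library, for 4 libraries of 1 mouse each, held a gene symbol and a value for 12408 genes, the same genes in each. The submitters' processing notes name CASAVA, HISAT2, edgeR and the mm10 build, without versions, settings or roles. The counter, the annotation and the filter on genes are not given in the sources used here.

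The deposited values are log2 CPM, as read from the values themselves, since the file headers give only the library name. On the linear scale they fall on a fixed grid in each library. The grid shows that 1 read, scaled by library size, was added to each gene before the logarithm and that library sizes carried a scaling factor. Size factors computed here by the trimmed mean of M values (TMM) differed from those in the files by at most 0.0969%. Every listed gene exceeded 1 CPM in at least 2 libraries, and 567 genes did so in exactly 2. Reads were recovered by dividing by the grid step. Between 88.6% and 89.0% of genes per library had whole reads (within 0.01), and 2449 genes (19.7%) had parts of reads in some library, meaning that reads were shared between genes or positions. One read was worth 0.371 CPM in CT baseline, 0.499 in CT TAC, 0.612 in cKO baseline and 0.544 in cKO TAC. The top 10 genes took 17.7%, 16.7%, 15.8% and 14.1% of the reads. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 7.71 to 21.0).

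Samples were grouped by the genotype and surgery in the labels. For each pair of libraries the log2 ratio is the difference of the deposited values, which understates the ratio of genes with few reads because of the added read. Clopper-Pearson 95% intervals of the ratio were computed from the recovered reads, rounded, and the effective library sizes. They cover counting error only, and reads amplified by PCR are not independent molecules. A gene passed when it was at least 2-fold apart and its interval excluded 1. A gene with 0 reads in 1 library was set against a floor of 3 reads per library, and its ratio is given as a lower bound. Such a gene passes on the deposited ratio, so its bound can lie under 2-fold. All 12408 genes had a mean CPM of at least 1, so that filter removed none.

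The models over all 4 libraries were planned as count tests. The edgeR test was not run because the files hold log2 values and the reads recovered from them were not whole for 2449 genes, and limma (version 3.58.1, R 4.3.3) with a mean-variance trend was fitted to the deposited log2 CPM instead. The design had an additive term for genotype and one for surgery, which leaves 1 residual degree of freedom and 2 mice per side, and the calls are at a Benjamini-Hochberg adjusted p under 0.05. With 1 mouse per group, the residual of a gene is the difference between its 2 genotype effects. Spread between mice of the same group was not measured. The p-values rest on that residual and, more heavily, on variance shared across genes (10.1 prior degrees of freedom against 1 residual). On simulated data for the genotype over 12408 genes, with a coefficient of variation of 0.2 and 200 changed genes, the fit recovered 90.3 of 100 genes changed 4-fold and 25 of 100 changed 2-fold, with 4.67 false calls per run over 3 runs. The simulation gave every gene the same coefficient of variation. It held no TAC effect and no difference between the genotype effects of the 2 states, so its rates do not carry over to the real fit.

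The comparisons, the named-gene rule, the gene lists and the alternatives, except those described as chosen later, were fixed before the data were examined. The lists cover Hippo components, YAP/TEAD targets, stress and fetal genes, adult sarcomere, calcium and ion handling, fatty acid oxidation, oxidative phosphorylation with the TCA cycle, glycolysis, cell cycle, the oncostatin M and gp130 response, dedifferentiation, extracellular matrix, Nrf2 antioxidant targets, the integrated stress response, immediate early genes, circadian genes, interferon response and p53 targets. Marker lists cover endothelial, fibroblast, mural, macrophage, lymphocyte, neutrophil, erythroid, atrial, Schwann and neural, adipocyte, mesothelial and skeletal muscle cells, and all ribosomal protein genes form a further list. In each pair, a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. As a further setting, chosen after seeing the data, the list mean was set against the range of the means of random lists, widened by the square root of 1 plus the estimated correlation times the other genes in the list. That correlation comes from camera, rests on 1 residual degree of freedom and was taken as 0 where negative. On 1 degree of freedom it reflects only how a list's genes split in the sign of their residual. A list whose genotype ratios shift the same way between states therefore widens its own range. Where the correlation was taken as 0, the range was not widened. Over both states, camera (limma) was run with a preset correlation of 0.01 and with an estimated one, which leaves its test 1 degree of freedom. Calls adjusted over the list alone stand beside those over all genes.

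For each pair of libraries the named genes are the 10 with the largest positive and the 10 with the largest negative log2 ratio among passing genes with a mean CPM of at least 5, leaving out Gm and Rik models, pseudogenes and globins. For each limma result they are the 10 largest called genes in each direction that moved the same way in both pairs, and for the difference between genotype effects the 5 largest in each direction. One gene that meets this rule is not reported here. Members of the lists are named as examples. Sex-linked genes (Xist, Ddx3y, Kdm5d, Uty and Eif2s3y) were not analysed here.

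Alternatives were total count scaling, median-of-ratios size factors, a mean CPM of at least 5, a fold threshold of 1.5, an interval wholly beyond 2-fold, the mean of a list, limma-voom on recovered reads, a fit without the other factor, and that fit with each library left out in turn, since the additive fit to 3 libraries has no residual degree of freedom. Removal of the added read (0.5 read added instead), leaving out genes with shared reads, the widened range for lists and a mean CPM of at least 50 were chosen after seeing the data. Gene positions come from the mm10 annotation, where 593 of 601 named genes and list members had 1 position. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.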

Results

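Gene expression was measured by RNA sequencing in whole hearts of 4 mice, each 3 months old and of the C57BL/6 strain. Mice labelled CT carried floxed copies of the Hippo pathway gene WW45, listed under its symbol Sav1. Mice labelled cKO also carried a Cre recombinase driven by the alpha-myosin heavy chain promoter, which deletes the floxed gene in cardiomyocytes. One mouse of each genotype was at baseline, and the other had undergone 4 weeks of transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. Each of the 4 groups therefore held 1 library, and the 2-library comparisons compare libraries, not conditions, with no replicate check and no p-value. The libraries held 2796547 recovered reads in CT baseline, 2064655 in CT TAC, 1587840 in cKO baseline and 1772153 in cKO TAC, over 12408 listed genes. The median gene had 48 reads in the deepest library and 30 in the shallowest. Intervals given below are 95% counting intervals and leave out the variation between mice. Among the genes named below, Postn, Timp1, Nppb, Xirp2, Atp2a2, Cd163, Kcnj3, Whrn, Celsr2, Qsox2 and Ano5 had reads partly shared with other places, so their values are uncertain.

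Sav1, a scaffold protein that activates the Hippo kinases, was the check of the genotype labels. It lies on mm10 chromosome 12 from 69965012 to 69987002 and had 49.3 CPM (interval 41.3 to 58.4) in CT baseline and 39.8 (30.7 to 50.7) in cKO baseline. Under TAC it had 35.4 CPM (27.7 to 44.7) in the library labelled CT and 46.2 (36.9 to 57.2) in the library labelled cKO. The log2 ratio of cKO to CT was -0.31 at baseline and 0.38 under TAC, so Sav1 was not lower in the library labelled cKO TAC. In limma's fit over all 4 libraries Sav1 differed between the genotypes by 0.04 (log2, SE 0.26, adjusted p = 0.987). Gene-level values cannot show whether the floxed exons lost their reads, and only cardiomyocytes carry the deletion, so the values check the labels weakly. Every genotype direction below compares libraries as labelled.

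**Figure D1:**
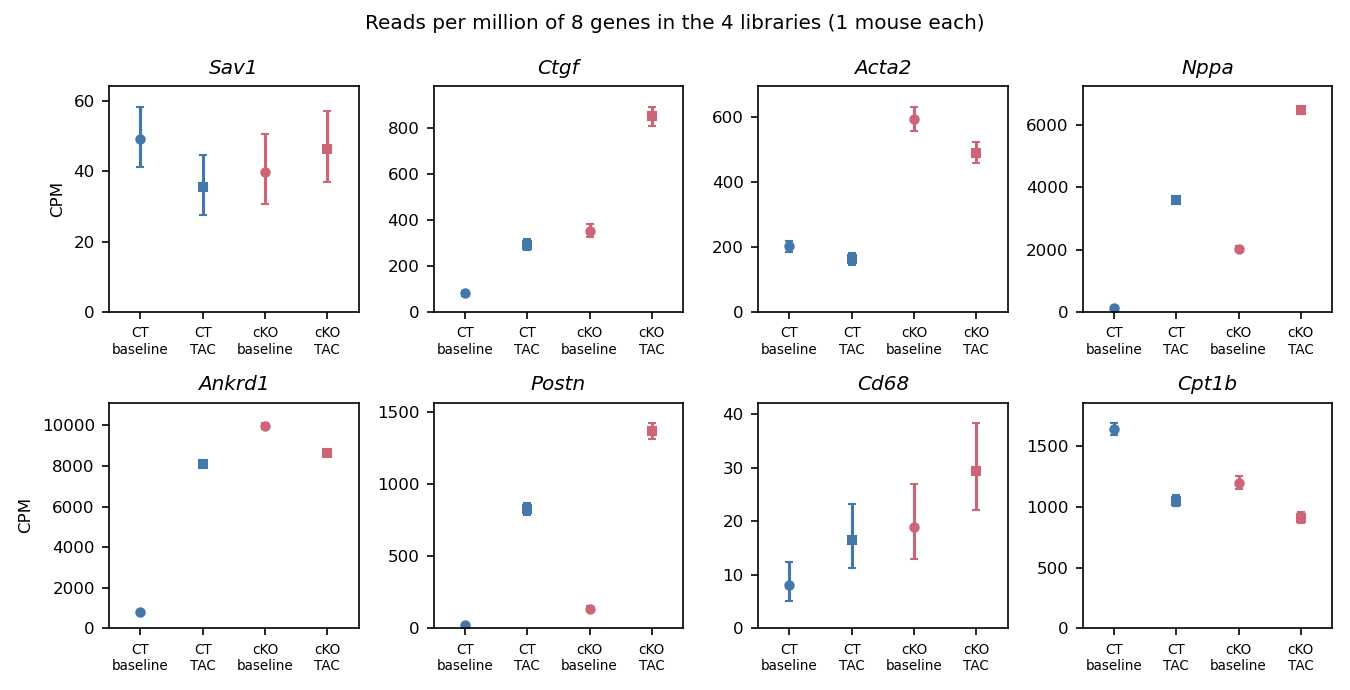
CPM (linear axis from 0) of 8 genes in the 4 libraries, 1 mouse each, with 95% Poisson counting intervals as bars; circles are baseline, squares TAC, blue CT and red cKO. Sav1 overlaps between genotypes, Ctgf and Acta2 are higher in both cKO libraries than in the CT library of the same state, and Ankrd1 is lower in CT baseline than in the other 3 libraries.

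The first question was how the CT library after TAC differed from that at baseline. No library is labelled as sham-operated, so effects of the operation and of the pressure load cannot be told apart. In CT mice, matrix genes had the largest ratios of the TAC library to the baseline library. Thrombospondin 4 (Thbs4; mm10 chromosome 13, 92751590 to 92794818) was 6.09 log2 units higher, with 8 reads at baseline and 470 under TAC. Cilp, a matrix protein of cartilage and scar, was 5.54 higher, and periostin (Postn), secreted by activated fibroblasts, was 5.09 higher. The natriuretic peptide gene Nppa was 4.79 higher (7201 reads against 349). At the other end stood Ces1d, a triglyceride hydrolase, at -2.95 (716 reads against 68), and Lrrc52, an auxiliary subunit of potassium channels, at -5.04 (264 reads against 5).

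In all, 1333 of 12408 genes were at least 2-fold apart in CT with an interval that excluded 1, 752 higher under TAC and 581 lower. The 10 highest also included Comp (5.26), Wisp2 (4.94) and Fmod, which had 1 read at baseline and 62 under TAC (ratio interval 14.4 to 3350). Cthrc1 and Atp6v0a4 had 0 reads at baseline and were at least 16.6-fold and 15.7-fold higher, counting 3 reads as the floor. Sumo2 had 3 reads at baseline and 83 under TAC (ratio interval 12.3 to 184). It has close copies elsewhere in the genome, so its value is uncertain. Among the 10 lowest were also the interferon-induced GTPase gene Gbp6 (-3.23), Scand1 (-3.04), Slc10a6 (74 reads against 6), Fam107a (-2.98, ratio interval 0.0195 to 0.309), Lamb3 (-3.18, 0.00897 to 0.3), Dixdc1 (-2.93, 0.02 to 0.317) and the cadherin gene Cdh22 (-3.01, 0.0101 to 0.341). These 4 had 2 or 3 reads in the TAC library, and Dixdc1 had shared reads.

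Of the 34 extracellular matrix genes, 29 were at least 2-fold higher in the CT TAC library, none was lower by that much, and 5 did not pass. The list's median log2 ratio was 2.28, above the central 95% range of 10000 random lists matched on expression. Collagens Col1a1 (2.63) and Col3a1 (3.48) were among those higher. Fibroblast markers had a median of 0.99 (7 of 14 passing, among them Mfap4 at 3.93 and Lum at 2.52), and macrophage markers a median of 0.79 (4 of 18 passing). The stress and fetal gene list had a median of 1.67, with 7 of 12 measured genes passing: skeletal alpha-actin Acta1 was 3.82 higher, Ankrd1 3.29, Nppb 2.64 and Xirp2 2.27. Cell cycle genes had a median of 0.73 (7 higher and 1 lower of 32), with Cdk1 at 2.83, and interferon response genes a median of 0.47 with 1 of 18 passing. The dedifferentiation list, which includes embryonic and smooth muscle cytoskeletal genes, had a median of 0.56 (5 of 15 passing).

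Fatty acid oxidation genes had a median of -0.68 in this pair, and 9 of 28 were at least 2-fold lower while 19 did not pass, among the 9 the uncoupling protein gene Ucp3 (-2.27), the acyl-CoA thioesterase gene Acot2 (-2.24), the pyruvate dehydrogenase kinase gene Pdk4 (-2.04) and the receptor gene Ppara (-1.39). Calcium and ion handling genes had a median of -0.63, but only 3 of 24 were at least 2-fold lower, with Jph2 at -1.28, Kcnj2 at -1.20 while Atp2a2, the calcium pump of the sarcoplasmic reticulum, at -0.98 did not pass. The integrated stress response list (median -0.53), the immediate early genes (-0.61), the oncostatin M and gp130 response (-0.45) and the erythroid markers (-0.57) also lay below the central 95% range of their random lists. By the list mean, immediate early genes (-0.14), the oncostatin M and gp130 response (-0.23) and erythroid markers (-0.50) lay within it, and so did the integrated stress response (-0.16) at a mean CPM of at least 5. Oxidative phosphorylation and TCA cycle genes (-0.18), Hippo components (0.11) and YAP/TEAD targets (0.18) lay within it. In all, 14 of 29 lists with at least 3 measured genes lay outside the central 95% range of their random lists. By the list mean, with that range widened for the estimated correlation between a list's genes, 7 did. Fatty acid oxidation (-0.79), macrophage (0.77), dedifferentiation (0.73), interferon (0.48) and ribosomal protein genes (0.26) then lay within it. Their correlation is measured on the same 4 libraries, so this does not show that these lists were unshifted. YAP/TEAD targets, with a mean of 0.45, came to lie above the plain range. It was not widened for them, since their estimated correlation was negative (-0.0105). The same holds for calcium and ion handling, cell cycle and integrated stress response genes, also among the 7.

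The same comparison in the libraries labelled cKO gave 811 genes at least 2-fold apart, 460 higher under TAC and 351 lower. Angptl7, an angiopoietin-like secreted protein, led with 81 reads under TAC against 2 (ratio interval 9.65 to 302). Wisp2 was 4.28 log2 units higher, Thbs4 3.71, Comp 3.39 and Postn 3.33. Nppa was 1.67 higher and Ankrd1 did not pass (-0.21). Lower in cKO TAC were the chemokine gene Ccl2 (-2.42), Ckmt1 (-2.64), the macrophage lectin gene Mgl2 (-2.82) and Hyou1, a chaperone of the endoplasmic reticulum (-2.28).

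The 10 highest further held Fmod (4.10, ratio interval 6.21 to 199.6) and Cthrc1 (3.15, 3.02 to 104), each with 2 reads at baseline, Ttr with 1 (3.68, 3.64 to 913), Pdlim3 (3.40) and Col4a3, which had 0 reads in cKO baseline and was at least 5.93-fold higher. The 10 lowest further held Rtn4r with 3 reads under TAC (-3.15, 0.0174 to 0.286), Thap2 with 1 (-2.68, 0.00205 to 0.625), Gal3st3 (-2.39), Klhdc7a (-2.30), and 2 genes with 0 reads under TAC. These were Cdh22, at least 4.87-fold lower, and Ano5, at least 4.50-fold lower. Extracellular matrix genes had a median of 1.27, with 21 of 34 passing and none lower, and fibroblast markers a median of 0.52 (6 of 14). Stress and fetal genes had a median of 0.65 (2 of 12 passing, Nppa and Rcan1), cell cycle genes 0.36 (5 of 32) and the dedifferentiation list 0.34 (2 of 15). Calcium and ion handling genes had a median of -0.51 and fatty acid oxidation genes -0.26. Within the latter Pdk4 was higher (1.27). Macrophage markers had a median of -0.12, within the range of random lists, and the antioxidant Nrf2 targets (0.24) and erythroid markers (0.52) lay above it. In all, 10 of 29 lists lay outside the range, and 5 by the list mean with the widened range. Stress and fetal (0.54), dedifferentiation (0.46), fatty acid oxidation (-0.19), Nrf2 (0.35), erythroid (0.58) and ribosomal protein genes (0.12) then lay within it, and neutrophil markers (-0.82) came to lie below. For neutrophil markers, calcium and ion handling and cell cycle genes the range was not widened, since their estimated correlation was negative.

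Across both genotypes, limma called 226 genes for TAC, of which 161 rose and 65 fell (limma-trend, Benjamini-Hochberg adjusted p under 0.05, 2 TAC against 2 baseline mice with a genotype term). Thbs4 rose by 4.90 on the log2 scale (SE 0.43, adjusted p = 0.000387), Wisp2 by 4.61 (SE 0.32, adjusted p = 0.000227) and Postn by 4.21 (SE 0.32, adjusted p = 0.000242). Fmod, Angptl7, Comp, Cthrc1, Cilp, Ltbp2 and Atp6v0a4 also rose, by 3.54 to 4.64. Ces1d fell by 2.40 (SE 0.26, adjusted p = 0.0011). Cdh22, the Nogo receptor gene Rtn4r, Whrn, the chemokine gene Ccl9, the ephrin receptor gene Epha4, Celsr2, Prodh, Qsox2 and Rps27a also fell. Rps27a has processed copies in the genome, so its value is uncertain. By the naming rule, each of these genes moved the same way in both genotypes.

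Among the 34 matrix genes 23 rose over all genes tested and 27 when adjusted over the list alone, and none fell. Among 14 fibroblast markers 5 rose over all genes and 8 over the list alone. Of 12 stress and fetal genes Nppa, Nppb, Rcan1 and Xirp2 rose over all genes. Adjusted over the list alone 8 rose, and Hk2 fell. Of 24 calcium and ion handling genes, Hrc, Jph2 and Ryr2, the calcium release channel, fell over all genes, by 0.86, 0.99 and 0.77 log2 units, and 11 fell over the list alone. Of 28 fatty acid oxidation genes, Cpt2, Ppara and Acot2 fell over all genes, and 14 fell and 1 rose over the list alone. In the dedifferentiation list Anxa2, Krt18 and Vim rose, and in the cell cycle list Cdk1 rose (2.57, SE 0.38, adjusted p = 0.00803). Camera with its preset correlation placed 8 of 31 lists apart from the other genes. The lists of matrix, fibroblast, stress and fetal, dedifferentiation, cell cycle and ribosomal protein genes lay up, and calcium handling and fatty acid oxidation lay down. No call was left with an estimated correlation (adjusted p = 0.838 with an estimated correlation for each). That version has 1 degree of freedom and its lowest unadjusted p over the 31 lists was 0.0938, for calcium and ion handling genes with an estimated correlation of -0.0145, so it cannot tell whether the calls depend on the correlation of genes. Ribosomal protein genes went both ways, with 7 that rose and 3 that fell of 82. Without a genotype term limma called 20 genes for TAC. Leaving out CT baseline as well as that term put part of the genotype effect into the TAC difference. That fit therefore cannot show how far the calls rest on 1 mouse.

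The next question was how the library labelled cKO differed from CT at rest. The cKO mice carried the Cre transgene as well as the deletion, and no library is labelled as Cre without floxed WW45. Effects of Cre and of the deletion therefore cannot be told apart. Several cardiac stress genes were higher in the cKO baseline library than in CT baseline. Nppa (mm10 chromosome 4, 148000722 to 148002079) was 3.97 log2 units higher (interval 14.1-fold to 17.6-fold). Ankrd1, a stress-induced sarcomeric ankyrin repeat protein and YAP target (chromosome 19, 36111961 to 36120099), was 3.59 higher, with 16286 reads against 2231. The secreted stress cytokine Gdf15 was 3.27 higher and the metalloprotease inhibitor Timp1 had 106 reads against 20.7. Ccl2, which draws monocytes, was 3.35 higher (32 reads against 4). Sav1 itself was 0.31 lower in this pair and 0.38 higher under TAC, against the labels.

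In all, 628 genes were at least 2-fold apart at baseline, 404 higher in the library labelled cKO and 224 lower. Scaled to total counts the split was 491 higher and 173 lower. The other 5 of the 10 highest were Cilp (3.41), Ckmt1 (3.35), Klhdc7a (25 reads against 4), Sumo2 with 50 reads against 3 (ratio interval 8.89 to 138), and Lrp8 with 13 reads against 1 (ratio interval 3.22 to 912). Lower were Lrrc52 (-5.07), Klhl33 (-2.58), the glycolytic regulator Pfkfb1 (109 reads against 11), Cdo1 (-2.43) and smooth muscle gamma-actin Actg2 (-2.29). Eps8l1 and Ttr had 1 read each in cKO baseline against 31 and 21 (ratio intervals 0.00131 to 0.319 and 0.0019 to 0.489). Wfdc1 had 2 against 24 (0.0158 to 0.554). Col4a3 passed on the deposited values, but with 8 reads against 0 it was only at least 1.62-fold lower.

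Matrix and macrophage genes were higher together in this pair. Of 34 matrix genes 21 were at least 2-fold higher, none was lower by that much, and the median was 1.17. Tgfb2 (2.56), Postn (2.5), Tnc (2.46) and Col3a1 (2.08) were among them. Of 18 macrophage markers 12 passed, all higher, with a median of 1.21. They included Adgre1, which encodes F4/80 (1.87), Lyz2 (1.5), the complement gene C1qa (1.45) and Cd68 (1.17). Fibroblast markers had a median of 0.30, with 4 of 14 passing, while endothelial (-0.13) and mural markers (-0.11) lay within the range of random lists. Stress and fetal genes had a median of 0.71 (5 of 12 passing), the dedifferentiation list 0.50 (2 higher, Acta2 and Krt18, and 1 lower, Tagln, of 15) and the oncostatin M and gp130 response 0.32 (4 of 15: Timp1, Socs3, Lcn2 and Serpina3n). YAP/TEAD targets had a median of 0.25 with 5 of 20 passing, namely Ankrd1, Tgfb2, Ctgf (2.12), Nuak2 (1.55) and Ccdc80 (1.38). Cyr61, another YAP target, was at -0.21 and did not pass.

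All 28 fatty acid oxidation genes had a log2 ratio below 0 at baseline, with a median of -0.53, below the range of random lists. Their estimated correlation was 0.857, and with the range widened for it (-0.94 to 0.91) the list mean of -0.68 lay within. That correlation is measured on the change of the genotype ratios between states itself, so the widening cannot decide whether the list was shifted. Of the fatty acid oxidation genes Ucp3 (-2.20), Pdk4 (-2.0), Acot2 (-1.65) and Ech1 (-1.01) were at least 2-fold lower. All 34 oxidative phosphorylation and TCA cycle genes were also below 0, with a median of -0.30 and none past 2-fold, and their mean of -0.30 also lay within the widened range (-0.32 to 0.27). Adult sarcomere genes (median -0.00), calcium and ion handling (-0.15) and Hippo components (-0.01) lay within the range of random lists. In all, 13 of 29 lists lay outside it, and 8 by the list mean with the widened range. Matrix (1.35) and macrophage genes (1.27) were among the 8, and ribosomal protein genes (0.18), erythroid markers (0.16) and atrial markers (0.14) were not. Also among the 8 were YAP/TEAD targets, cell cycle genes and the oncostatin M and gp130 response. Their estimated correlation was negative, so their range was not widened.

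The CT baseline library enters both this comparison and that of TAC in CT. Across genes, which are not independent replicates, the genotype ratios at baseline and the TAC ratios in CT had a Pearson r of 0.470. Simulated unchanged groups sharing 1 control gave 0.415. The simulation drew genes independently and took its spread between mice from limma's fit to these same libraries. The covariance was 0.252 against 0.126 in the simulation, a difference of 0.126. That difference depends on the assumed spread, since spread between mice of the same group was not measured. Genes higher in both numbered 182, where independent lists would share 24.5, and 96 were lower in both against 10.5. How much of that excess comes from the shared library could not be split. The share of genes with the same sign was 64.0%, against 64.5% in the simulation.

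**Figure D2:**
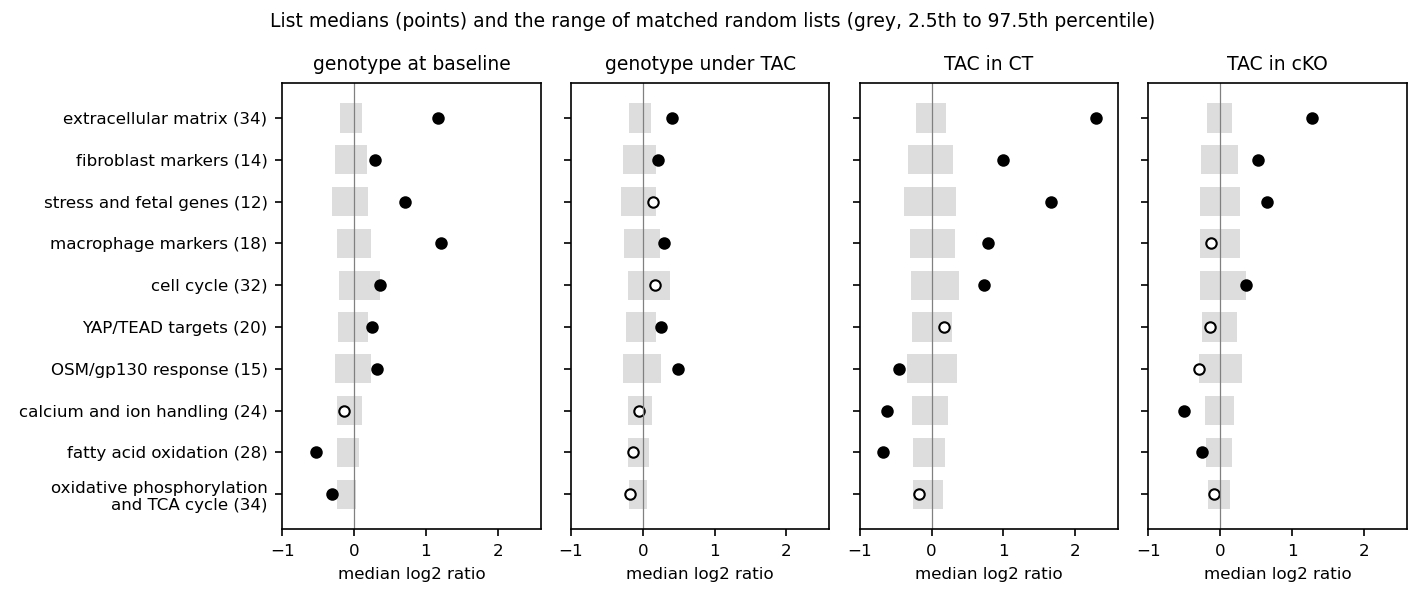
Median log2 ratio of 10 gene lists (points; number of measured genes in brackets) in the 4 comparisons of 2 libraries, with the central 95% range of 10000 random lists matched on expression (grey); filled points lie outside it. Extracellular matrix genes lie above it in all 4 panels, at 1.17, 0.40, 2.28 and 1.27, where the range takes the genes of a list as independent.

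It was then asked how the genotypes differed after TAC. The library labelled cKO TAC had more of the crosslinking enzyme gene Lox (2.86 log2 units, 39 reads against 5), the galectin gene Lgals3 (2.80) and the stearoyl-CoA desaturase gene Scd4 (3.20, 92 reads against 10). Serpina3n and Lcn2, secreted proteins of the acute phase, were each 1.95 higher. Acta2 was 1.60 higher and Ctgf 1.55. Skeletal alpha-actin Acta1 was lower (-1.69), as was Actg2, with 3 reads against 75 (ratio interval 0.00879 to 0.132). Sav1 was 0.38 higher in this library, against its label.

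In all, 621 genes were at least 2-fold apart under TAC, 363 higher in the library labelled cKO and 258 lower. Scaled to total counts the split was 479 higher and 179 lower. The 10 highest further held Lrrc52 (2.58), Usmg5 (2.39), Il17ra (3.13, ratio interval 3.51 to 57.5) and Fam107a (2.52, 2.15 to 38.2) with 3 reads each in CT TAC. Fam46b (2.93, 2.65 to 96.1), Zfp771 (2.86, 2.5 to 91.6) and Necap2 (2.79, 2.35 to 87.1) had 2 reads each there. The 10 lowest further held the sodium pump gene Atp1a4 (-3.26), Mfap3l (-2.92), Aqp8 (-2.52), Rpl27 (49 reads against 306), Pabpc4 (-2.44), Eps8l1 (-2.34), B3galt2 (-2.28), Pigh with 2 reads (-2.34, 0.0161 to 0.625), and Ano5, which had 0 reads and was at least 2.75-fold lower. Pabpc4 and Mfap3l had reads shared with other places, and Rpl27 has processed copies, so these values are uncertain.

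Matrix genes lay above random lists under TAC (median 0.40), with 5 of 34 passing, but with the range widened for their estimated correlation of 0.483 (-0.66 to 0.62) their mean of 0.41 lay within. The 5 were Lox, Tgfb3 (1.12), Mfap5 (1.1), Eln (1.09) and Timp1 (1.07). Macrophage markers had a median of 0.29, with Lgals3 and Cd163 (1.16) passing of 18, and their mean of 0.34 lay within the widened range (-0.90 to 0.93). Fibroblast markers had a median of 0.21, with none passing of 14. The oncostatin M and gp130 response had a median of 0.49, and 5 of 15 passed: Serpina3n, Lcn2, Il6ra, Timp1 and the receptor gene Osmr (1.01). YAP/TEAD targets had a median of 0.25, with Ctgf, Amotl2 (1.36) and Nt5e (1.17) passing of 20. Stress and fetal genes (0.15) and fatty acid oxidation genes (-0.13) lay within the range. The antioxidant Nrf2 targets had a median of 0.38, with G6pdx (1.42), Hmox1 (1.36), Nqo1 (1.29) and Gclm (1.06) passing of 19. Integrated stress response genes (0.51; Asns 1.96) and immediate early genes (0.71) also lay above random lists, and glycolysis genes (-0.26) below. Erythroid markers were higher (1.60, 5 of 7 passing); 4 of the 7 are beta-globin entries, and these hold only 2 distinct sets of values. In all, 10 of 29 lists lay outside the range, and 6 by the list mean with the widened range. Immediate early genes (mean 0.74), glycolysis genes (-0.16) and fibroblast markers (0.16) then lay within it, and adipocyte markers (-0.72) came outside. The last 3 did so with the plain range too. For YAP/TEAD targets, the oncostatin M and gp130 response, integrated stress response genes and adipocyte markers the range was not widened. Their estimated correlation was negative.

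Over both states, limma called 3 genes for the genotype, and each rose in the libraries labelled cKO. Ctgf, a secreted matricellular protein and YAP target, rose by 1.83 on the log2 scale (SE 0.19, adjusted p = 0.00913). Acta2, smooth muscle alpha-actin (chromosome 19, 34241090 to 34255590), rose by 1.58 (SE 0.17, adjusted p = 0.00913), with ratios of 1.56 at baseline and 1.60 under TAC. Prg4, the lubricant glycoprotein lubricin, rose by 1.51 (SE 0.19, adjusted p = 0.0255). Its reads were partly shared with other places, so it is uncertain. With no surgery term the Ctgf difference stayed at 1.83 while its SE rose from 0.19 to 0.6, since TAC then enters the spread (adjusted p = 0.999). With 1 library left out as well as that term, the groups were unbalanced and part of the TAC effect entered the genotype difference itself. The Ctgf difference was then 0.92 without CT baseline, 1.2 without cKO TAC and 2.75 without CT TAC. Over the alternatives that kept all 4 libraries the adjusted p of Ctgf ran from 0.0023 to 0.999. Ctgf also rose with TAC, by 1.55 (SE 0.19, adjusted p = 0.00272). The near-identical paralog Actg2 was lower in both cKO libraries but was not called (-3.23, SE 0.45, adjusted p = 0.05, just over the threshold), and reads could pass between the 2 actins. Actg2 was called at a mean CPM of at least 5 (adjusted p = 0.0164) and without genes with shared reads (0.046). The latter fit also held Acta2 (0.00728), so neither actin had parts of reads in any library. Over the alternatives that kept all 4 libraries the adjusted p of Actg2 ran from 0.0164 to 0.999.

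Adjusted over the list alone, 14 of 34 matrix genes rose with the genotype, among them Timp1 (2.04), Postn (1.61) and Mfap5 (1.39), where none was called over all genes. Likewise 6 of 18 macrophage markers rose over the list alone (Cd68, Csf1r, Lyz2, Mrc1, C1qa and Lgals3), and 4 of 12 stress and fetal genes (Nppa, Nppb, Ankrd1 and Gdf15). Serpina3n, Timp1 and Lcn2 rose of the 15 oncostatin M and gp130 genes, and Ctgf, Ankrd1, Ccdc80 and Tgfb2 of the 20 YAP/TEAD targets. No fatty acid oxidation or oxidative phosphorylation gene was called. Camera with its preset correlation placed 16 of 31 lists apart for the genotype. The 13 that lay up were matrix, macrophage, fibroblast, erythroid, stress and fetal, YAP/TEAD, oncostatin M, dedifferentiation, cell cycle, integrated stress response, immediate early, Nrf2 and ribosomal protein genes. The 3 that lay down were fatty acid oxidation, oxidative phosphorylation and TCA cycle, and glycolysis. No call was left with an estimated correlation (adjusted p = 0.689 with an estimated correlation for each). On 1 degree of freedom the lowest unadjusted p was 0.14, for YAP/TEAD targets with an estimated correlation of -0.0105, so this decides no more than for TAC. Hippo components (median 0.04), adult sarcomere (-0.01), calcium and ion handling (-0.05), circadian (-0.04), interferon (0.02), endothelial (-0.01) and atrial genes (-0.08) were not placed apart. The lists with 2 measured genes, lymphocyte (0.58) and mesothelial markers (0.83), were not either.

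The smaller marker lists were also compared in the 4 pairs, in the order genotype at baseline, genotype under TAC, TAC in CT and TAC in cKO. Medians were 0.79, 0.36, -0.53 and -0.51 for 6 neutrophil markers, and -0.01, 0.51, -0.24 and -0.10 with members at 0 reads set to their bounds. They were -0.46, 0.67, -1.0 and -0.01 for 5 Schwann and neural markers, and the last 2 were -0.59 and 0.25 at the bounds. Skeletal muscle markers had 0.33, 0.62, 0.47 and 0.13, and the last 2 were 0.24 and 0.00 at the bounds. In the same order the medians were 0.01, -0.11, 0.56 and 0.22 for adipocyte markers and 0.11, 0.09, 0.01 and 0.05 for p53 targets. Atrial markers had -0.42, -0.06, 0.08 and 0.14. Atrial markers at baseline lay below random lists (1 of 8 higher, Nppa, and Kcnj3 and Tbx5 lower), and their mean was 0.14, of the other sign. Median and mean also differed in sign for YAP/TEAD targets in cKO under TAC (-0.15 and 0.09), for Hippo components at baseline (-0.01 and 0.06) and for mural markers at baseline (-0.11 and 0.04). Ribosomal protein genes had 0.15, 0.04, 0.33 and 0.13.

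The fit has 1 residual degree of freedom and counts any difference between the 2 genotype effects as spread, and 964 genes had an unadjusted p under 0.05. Fits with 1 library left out also dropped the surgery term, and their unbalanced groups let part of the TAC effect into the genotype difference. They therefore cannot show how far the calls rest on 1 mouse.

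The genotype ratios of the 2 states, which share no library, were then compared across genes. Pearson's r was 0.079 and Spearman's rho 0.088, and 54.2% of genes had the same sign. Of the genes at least 2-fold apart, 38 were higher in cKO in both states, where independent lists would share 11.8, and 13 were lower in both against 4.66. Another 34 went opposite ways, against 15.0. The TAC ratios of the 2 genotypes had an r of 0.309 and a rho of 0.305, with 165 genes higher in both against 27.9, 69 lower in both against 16.4 and 25 opposite against 42.8.

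Lrrc52, Cdo1, Zfp771, Wfdc1 and Ttr had the largest positive difference between the genotype ratio under TAC and that at baseline, from 7.65 log2 units for Lrrc52 to 3.82 for Ttr. Atp1a4 (-4.91), Sumo2 (-4.59), Lrp8 (-4.12), Nmrk2 (-3.79) and Ankrd1 (-3.50) had the largest negative. Ankrd1 was 3.59 higher in cKO at baseline and 0.09 under TAC. Its reads in CT baseline were 2231, while the other 3 libraries held 15857 to 16286. No test of these differences was possible, since no residual degree of freedom is left.

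**Figure D3:**
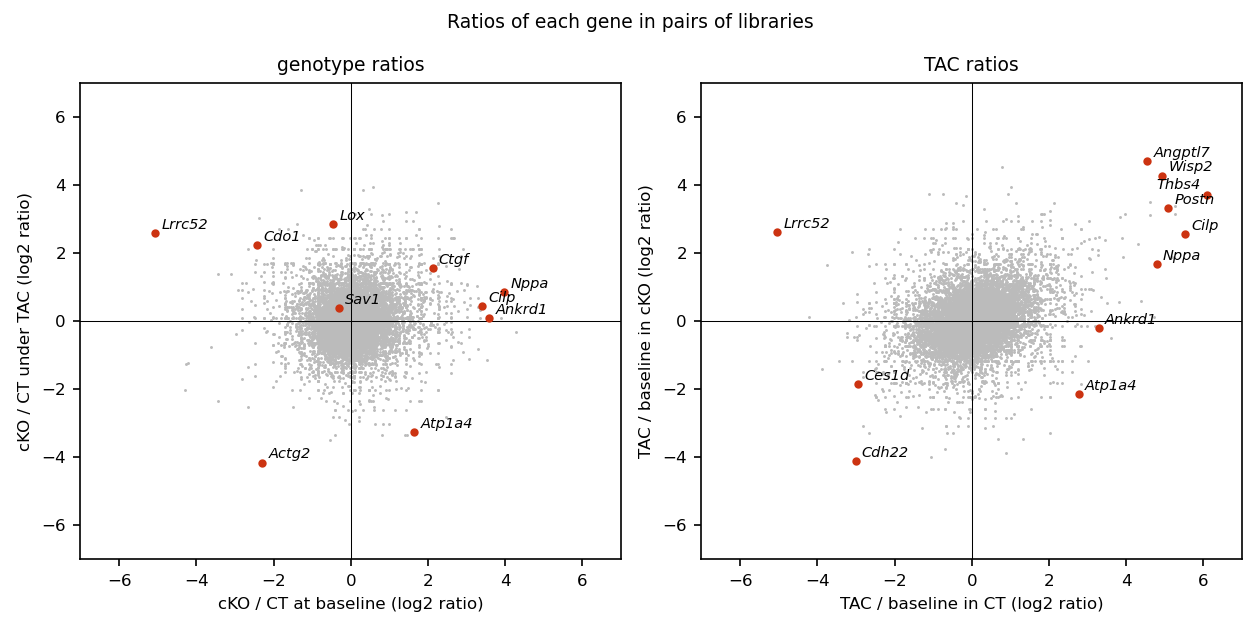
Log2 ratio of each of 12408 genes (grey points; named genes in red) for cKO over CT under TAC against baseline (left) and TAC over baseline in cKO against CT (right). Pearson's r across genes is 0.079 on the left and 0.309 on the right.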

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

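The test of a label swap and the 3 tests on the CT baseline library were chosen after the results were seen. The limits of the test on abundant genes were written before it, but its minimum of 50 CPM was chosen after seeing the data. Among the named genes and list members, 25 single-gene results passed in opposite directions in 2 pairs of libraries without a shared library, and 1 list lay outside its range on opposite sides. Atp1a4, Cdo1, Lrrc52, Pdk4, Wfdc1 and Zfp771 are counted both for genotype and for TAC, which are the same contrast of the 4 libraries. Some genes, such as Lrrc52 and Atp1a4, were named for the size of that contrast, so their place here follows partly from the naming rule. None of these differences was tested, since 1 mouse stands behind each library.

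Between genotypes as labelled, 34 of 12408 genes passed in opposite directions at baseline and under TAC, and 15 of them are named genes or list members. Among heart muscle and metabolic genes these were Acta1 (1.58 and -1.69), Nmrk2 (2.65 and -1.15), Pdk4 (-2.0 and 1.31), Pdlim3 (-2.04 and 1.59), Cdo1 (-2.43 and 2.24) and Atp1a4 (1.65 and -3.26). Among transcription factors and immune genes they were Cebpb (-1.25 and 1.51), Egr1 (1.44 and -1.08), Mgl2 (1.01 and -1.49) and Cfd (2.47 and -2.83). Cfd had 1, 6, 7 and 0 reads, so its ratios are at the floor. The others were Atp1a4 (1.65 and -3.26), Lrrc52 (-5.07 and 2.58), Fam107a (-1.25 and 2.52), Slc10a6 (-1.0 and 2.12), Wfdc1 (-2.45 and 1.80) and Zfp771 (-1.40 and 2.86).

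With TAC, 25 genes passed in opposite directions in CT and in cKO, and 10 of them are named genes or list members. These were Aldh1a2 (1.79 and -1.25), Atp1a4 (2.77 and -2.14), B3galt2 (1.86 and -1.39), Mfap3l (1.21 and -1.55) and Rps24 (-1.17 and 1.05). The same holds for Cdo1 (-2.70 and 1.97), Lrrc52 (-5.04 and 2.61), Pdk4 (-2.04 and 1.27), Wfdc1 (-1.92 and 2.34) and Zfp771 (-2.66 and 1.61). The erythroid list had medians of -0.57 and 0.52, and these differences were not tested either. By the list mean with the widened range, the erythroid list lay within it both times (-0.50 and 0.58).

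Sav1 was not lower in the library labelled cKO TAC than in CT TAC. If the 2 TAC libraries carried each other's labels, genes higher in cKO at baseline would tend to be lower in the library labelled cKO TAC. Of the 404 genes at least 2-fold higher at baseline, 247 (61.1%) were higher there. Genes move together within a mouse, so a share of this size from 1 mouse per side does not exclude a swap. A wrong label involving a sample from outside the series, and RNA of cells without the deletion, also stay open, since exon counts were not analysed here.

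The genotype ratios of the 2 states hardly correlated across genes. If counting noise were the cause, abundant genes would correlate well. Among the 3093 genes with a mean CPM of at least 50 Pearson's r was 0.1294, below the limit of 0.2 written for this test. The minimum of 50 CPM was chosen after seeing the data. For these genes the low r argues against counting noise as its cause. Differences between single mice unrelated to genotype, and a genotype effect that depends on load, could each give this, and with 1 mouse per group neither was tested.

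Matrix, macrophage and fatty acid oxidation genes lay outside the range of random lists at baseline. If the CT baseline library alone stood apart, the TAC pair, which does not hold it, would show no shift. The list means in that pair were 0.41 for matrix, 0.34 for macrophage and -0.08 for fatty acid oxidation genes, against 1.35, 1.27 and -0.68 at baseline. With the range of random lists widened by the estimated correlation of each list's genes (0.483, 0.582 and 0.857), each mean in the TAC pair lay within it, and at baseline matrix and macrophage genes lay outside it while the call of fatty acid oxidation genes was lost. That correlation is measured on the difference between the 2 pairs itself, since 1 residual degree of freedom is left, so the test decides nothing. A CT baseline library that differs for other reasons, and a genotype effect, both stay open as possible explanations for all 3 lists.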

How the results depend on the processing

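Removal of the added read, leaving out genes with shared reads, the widened range for lists and the minimum of 50 CPM were chosen after seeing the data. No paired analysis was possible because each group held 1 library and the labels carry no replicate numbers.

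With a threshold of 1.5-fold, 1337 genes were apart between genotypes at baseline, 1497 under TAC, 2636 with TAC in CT and 1744 with TAC in cKO. With the whole interval beyond 2-fold these counts were 116, 70, 306 and 126.

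For the genotype over both states, limma called 9 genes at a mean CPM of at least 5 and 8 with limma-voom, and each set held the 3 genes of the report. Without a surgery term limma called 0 (345 at an unadjusted p under 0.05). Leaving out 1 library in turn, also with no surgery term, gave 0 to 89 calls: 13 without CT baseline, of the 3 genes Acta2 alone among them, 89 without CT TAC, and 0 without cKO baseline (300 at an unadjusted p) or cKO TAC (222). For TAC, limma called 20 genes without a genotype term, and 9 to 87 with 1 library left out as well as that term (9 without CT baseline, 35 without CT TAC, 87 without cKO baseline, 59 without cKO TAC). Leaving out a library thus changed 2 choices at once, because the additive fit to 3 libraries has no residual degree of freedom. The groups were then unbalanced, so part of the effect of the dropped factor entered the difference itself. Such counts do not show how far the calls rest on 1 mouse. These fits leave 1 library alone in a group and assume that it varies like the others.

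Across genes with a mean CPM of at least 50, r was 0.1294 for the genotype ratios and 0.5384 for the TAC ratios. Over all alternatives to the summary results, 64 values were similar and 26 moved. Some of the 64 could not differ, since a factor per library moves neither the correlations nor the place of a list among random lists. Of the checks on single genes 392 were similar, 72 lost their limma call, 1 moved and none changed sign. All 72 concern genes named for the limma results. Without a term for the other factor 18 of these calls were lost and 5 were kept. Ratios of 2 libraries counted as similar where they stayed within their counting interval, and the pass rule was not checked again.

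By the list mean, with the range widened by the estimated correlation, 8 lists lay outside it at baseline, 6 between genotypes under TAC, 7 with TAC in CT and 5 with TAC in cKO. Lists with a negative estimated correlation kept the plain range, so for them this was no second check. Single lists depended more on the setting. Atrial markers at baseline lay below random lists by the median (-0.42) but had the other sign by the mean (0.14) and at a mean CPM of at least 5 (0.032), inside the range both times. By the mean, erythroid markers at baseline (0.16), glycolysis (-0.16) and fibroblast markers (0.16) between genotypes under TAC, the oncostatin M response (-0.23), immediate early genes (-0.14) and erythroid markers (-0.50) with TAC in CT, and ribosomal proteins with TAC in cKO (0.12) came inside. At a mean CPM of at least 5, cell cycle genes at baseline (0.18) and with TAC in CT (0.38), the integrated stress response with TAC in CT (-0.16) and Nrf2 targets with TAC in cKO (0.21) did. Outside the range came p53 targets under TAC (0.49) and atrial markers with TAC in CT (-0.71) at that minimum. By the mean, so did adipocyte markers between genotypes under TAC (-0.72), YAP/TEAD targets (0.45) and Schwann markers (-1.11) with TAC in CT, and neutrophil markers with TAC in cKO (-0.82). Other lists that changed sign lay inside the range by the median. With camera, glycolysis (adjusted p = 0.0549) and cell cycle (0.0504) lost their genotype call under total counts, and cell cycle lost both calls at a mean CPM of at least 5 (0.104 for the genotype and 0.0732 for TAC). The lists that changed direction there were not called.

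The planned count tests of edgeR and DESeq2 were not run, since the reads recovered from the log2 values were not whole for 2449 genes; limma-voom was run on those reads instead. The comparison without a filter was not run because every gene passed the filter.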

Other observations

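A few clock genes differed between the libraries, although the circadian list as a whole was not shifted in 1 direction. In CT, Arntl, which encodes the clock activator BMAL1, was 2.29 log2 units lower under TAC (23 reads against 157), while Dbp was 2.93 and Per3 2.67 higher. With Bhlhe41 (1.45) and Nfil3 (-1.26) these were the 5 of 16 genes that passed in CT, and 11 did not. Among all genes 1333 of 12408 passed in that pair. In the libraries labelled cKO the ratios of Arntl, Dbp and Per3 were -0.37, 0.95 and 1.11, and Per3 was the single gene of the 16 to pass. Over both genotypes limma called Dbp (1.94, SE 0.40, adjusted p = 0.039) and Per3 (1.89, SE 0.41, adjusted p = 0.0471) as higher with TAC. The list lay within the range of random lists in all 4 pairs (median -0.15 and mean 0.18 with TAC in CT), and camera did not place it apart (adjusted p = 0.552 for TAC and 0.619 for the genotype). Members that move in opposite directions cancel in these measures, so they do not show that the list was unaffected. Arntl and Per3 had reads partly shared with other places. The hour of tissue collection was not analysed here.

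Hspa5 and Hyou1, both chaperones of the endoplasmic reticulum, were lower in the library labelled cKO TAC than in cKO baseline (-1.61 and -2.28). They were picked after their values were seen, and chaperones were not tested as a group. In CT both hardly differed with TAC (-0.16 and 0.02). The proliferation marker Mki67, from a list where 4 of 32 genes passed at baseline, was 1.51 higher in cKO baseline than in CT baseline and 2.25 higher with TAC in CT. Ribonucleotide reductase gene Rrm2 had 14 reads in cKO TAC against 2 in CT TAC. Perp and Ier3 were higher in cKO in both states (1.25 and 1.16 for Perp, 1.18 and 1.22 for Ier3), and each was called for the genotype by limma when adjusted over its list alone, though not over all genes (adjusted p = 0.151 and 0.21). Sav1 did not follow the labels under TAC, so these directions hold for the libraries as labelled.

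Genes with shared reads did not spread more than genes with whole reads. The median absolute log2 ratio was 0.306 against 0.329 between genotypes at baseline and 0.372 against 0.436 with TAC in CT.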
